A study of Mus musculus with 6 samples.

How the data were processed

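Polyadenylated RNA from B16F10 cells, a pigmented mouse melanoma line, was sequenced in 6 libraries, of which 3 came from control cells and 3 from cells treated with an extract of Polianthes tuberosa (tuberose). Per the labels, RNA was extracted from all samples at the same time with a column kit, and the libraries were sequenced on Illumina instruments by a commercial provider. The dose, the duration of treatment and any stimulation of pigmentation are not given in the sources used here, and no label says whether the replicates were separate cultures. The controls are titled control and their columns are named blank. Neither name says whether these cells received the solvent of the extract, so an effect of a solvent cannot be told apart from one of the extract. The p-values therefore measure only the spread between these samples, which may be technical.

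The deposited table holds unnormalised read counts per gene, 1 column per library, under Ensembl mouse gene identifiers. Per the submitters' processing notes, the tools used were fastp 0.22.0, HISAT2 2.2.0 and featureCounts 2.0.6. The notes list both a human and a mouse genome build (hg38 and mm39) with no role for either. The annotation release and the strand setting of the counting are not given in the sources used here, so counts of overlapping genes and of antisense genes are uncertain, as are those of genes with near-identical copies such as H2-K1, H2-D1, Hspa1b, Fth1 and Fdps. The table has 27067 gene identifiers, each with at least 1 count, and 0 rows that name no gene. The 6 columns were matched to samples through the library names in the labels, and 0 columns were left unmapped. Symbols, gene biotypes and exonic lengths were taken from GENCODE M21 (GRCm38), which gave a symbol to 26531 identifiers and none to 536, and labelled 15976 as protein coding. Because that assembly is not the listed mouse build, no coordinates are given.

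Library totals were 40129044, 31991473 and 34609536 counts for control replicates 1, 2 and 3, and 33002773, 33717357 and 31183728 for treated replicates 1, 2 and 3. Genes were kept by filterByExpr (minimum count 10, minimum total count 15), which left 15150 genes, and libraries were scaled by TMM factors. The comparison of treated with control libraries used the quasi-likelihood F test of edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3, two-sided, with group as the single term and Benjamini-Hochberg adjustment over the tested genes. An adjusted p under 0.05 was taken as a change. Expression levels in CPM, counts scaled to a common library total, were computed from the deposited counts with the TMM-scaled totals and are given as mean ± SD of 3 libraries. Log2 fold changes are treated over control, and their standard errors (SE) are the absolute log2 fold change divided by the square root of the F statistic. The biological coefficient of variation was 3.70%.

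A total of 35 gene lists with 755 different genes, some of them standing on several lists, was written before the data were examined. The 32 lists with at least 5 tested genes were tested with camera (limma 3.58.1) at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over these lists. Members passing the gene test were also counted adjusted over the list alone. Each list was tested again with an estimated correlation and with fry. With an estimated correlation camera uses the residual degrees of freedom of the 6 libraries, and with a preset one nearly as many as genes. Its p can therefore rise where the estimated correlation is not above the preset one. The fry test asks whether the genes of a list move on balance one way and does not compare them with other genes. The lists covered pigment cell genes, cAMP and MAPK signalling, stress responses, lipid synthesis, cell division and death, inflammation, metabolism, matrix and melanoma states, and markers of fibroblasts, immune cells, endothelial cells and keratinocytes.

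The rule for naming genes was also fixed before the data were examined. It takes 13 pigment and signalling genes whatever their result, and the 8 largest rises and 8 largest falls among changed protein-coding genes with a mean of at least 5 CPM, a symbol other than a predicted-gene name and all 3 treated libraries on the same side of all 3 controls. From each list it takes up to 4 changed members with the smallest p and up to 4 with the largest change. Genes named outside this rule are marked as chosen after their values were seen. Some genes that the rule takes, 1 of the 13 among them, are not reported here by name and stay in the fits and in the list tests.

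Alternatives chosen before the data were examined were size factors by the median of ratios, library totals without scaling factors, no filter, a filter at 1 CPM in 3 libraries, protein-coding genes only, the replicate number as a block, leaving out each library in turn, DESeq2 1.42.0, and the other list tests. Level-dependent offsets from cyclic loess were added after the data were seen. The fit was tested on simulated counts for the same 15150 genes, with 50 genes changed by each of 4 fold sizes. It recovered 42% of genes changed by 1.2-fold, 74% at 1.5-fold, 84% at 2-fold and 100% at 4-fold, and 6 of its 156 calls were unchanged genes. With 200 genes changed, its adjusted p threshold was stricter than that of the data, so these rates may understate detection here.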

Results

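Gene expression was measured by RNA sequencing in 6 libraries of B16F10 mouse melanoma cells, 3 from control cells and 3 from cells treated with tuberose extract. The deposited read counts summed to between 31183728 and 40129044 per library. The comparison addresses which genes differed between extract-treated and control cells. Of particular interest are those of pigment synthesis and of the cAMP/CREB and MAPK pathways named in the title of the series. Libraries of the same group were close to each other, with correlations of log2 CPM between 0.993 and 0.994 against 0.985 to 0.986 across groups. The first principal component separated the groups and carried 57.5% of the variance. Each pair of libraries within a group differed by more than sampling noise, with a chi-square per gene of at least 3.45, so that no pair was counted as 1 repeated library. This does not show whether they came from separate cultures.

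Treated cells had lower mRNA levels of most pigment genes, including the melanosome matrix gene Pmel, the pigment enzyme genes Dct and Tyr, and the pigment cell transcription factor genes Mitf and Sox10, while the pigment enzyme gene Tyrp1 was higher. The 3 pigment gene lists were lower than other genes with a preset correlation. They did not pass with an estimated correlation, a test with fewer degrees of freedom (adjusted p = 0.202, 0.126 and 0.0705). The list of pigment proteins also did not pass with level-dependent offsets (camera adjusted p = 0.0804). Genes of a JNK, p38 and AP-1 stress list, such as Klf4, Klf2, Gadd45a and Atf3, were higher. So were 24 of 26 genes of cholesterol synthesis and 17 of 26 genes of the oxidative stress response, with 1 and 6 lower. Most genes of DNA replication and mitosis were lower by modest amounts, and neither list passed with an estimated correlation (adjusted p = 0.0705 and 0.110). In total 8032 of 15150 tested genes changed (edgeR quasi-likelihood test with Benjamini-Hochberg adjustment), 3809 of them higher and 4223 lower in treated libraries. Most changes were small: the median absolute log2 fold change among changed genes was 0.30, and 80.0% of them changed by under 1.5-fold. Changes of at least 2-fold numbered 682, of which 631 were higher and 51 lower. The 51 lower genes became 30 with a filter at 1 CPM, 83 with no filter, 149 with level-dependent offsets and 93 without treated replicate 1, and the 682 became 392 with the filter at 1 CPM. The 631 higher genes became 362 with that filter and 383 with level-dependent offsets. With library totals in place of TMM factors the balance turned, with 5069 genes higher and 3045 lower among 8114 changed genes, and the share of higher genes was 62.5% against 47.4%. The groups did not overlap for 58.7% of tested genes, where chance gives 10%.

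Among 12 of the pigment and signalling genes fixed in advance, Pmel (ENSMUSG00000025359) fell most, from 4145 ± 87.6 to 2539 ± 28.5 CPM (SD, n = 3 per group), a log2 fold change of -0.71 ± 0.01 (SE, edgeR adjusted p = 1.46e-20). Dct (ENSMUSG00000022129), the dopachrome tautomerase gene, fell from 5132 ± 44.0 to 3797 ± 98.5 CPM (log2 fold change -0.43, edgeR adjusted p = 6.71e-17). Tyr (ENSMUSG00000004651), which encodes tyrosinase, the rate-limiting enzyme of melanin synthesis, fell by 20.7%, from 704 ± 23.8 to 558 ± 19.9 CPM (log2 fold change -0.33 ± 0.03, edgeR adjusted p = 1.61e-10). Tyrp1 (ENSMUSG00000005994) rose by 12.2%, from 5288 ± 188 to 5935 ± 276 CPM (edgeR adjusted p = 1.88e-06). Mitf (ENSMUSG00000035158), the master regulator of pigment cell genes, fell by 29.4%, from 473 ± 9.47 to 334 ± 7.96 CPM (log2 fold change -0.50 ± 0.02, edgeR adjusted p = 3.49e-14). Sox10 (ENSMUSG00000033006), a regulator of Mitf, fell from 461 ± 5.83 to 345 ± 3.59 CPM (log2 fold change -0.42 ± 0.02, edgeR adjusted p = 1.79e-13). In these genes all 3 treated libraries lay on 1 side of all 3 controls. Mlana (ENSMUSG00000024806) fell by 3.54% (log2 fold change -0.05 ± 0.02, edgeR adjusted p = 0.0213), but its sign turned with library totals (0.03) and with level-dependent offsets, where it passed as a rise (0.11, edgeR adjusted p = 1.43e-05). Its call was lost without control replicate 2, treated replicate 1 or treated replicate 2 (edgeR adjusted p = 0.0727, 0.0687 and 0.0966) and with the filter at 1 CPM (0.0926). Mc1r (ENSMUSG00000074037), the receptor for melanocyte-stimulating hormone, had a log2 fold change of 0.07 ± 0.03 (edgeR adjusted p = 0.0577), which passed under 6 alternatives: without treated replicate 1 (edgeR adjusted p = 0.0220), with library totals (1.50e-04), median-of-ratios factors (0.0400), the filter at 1 CPM (0.0171) or level-dependent offsets (1.16e-05, log2 fold change 0.18), and in DESeq2 (0.0475).

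**Figure D1:**
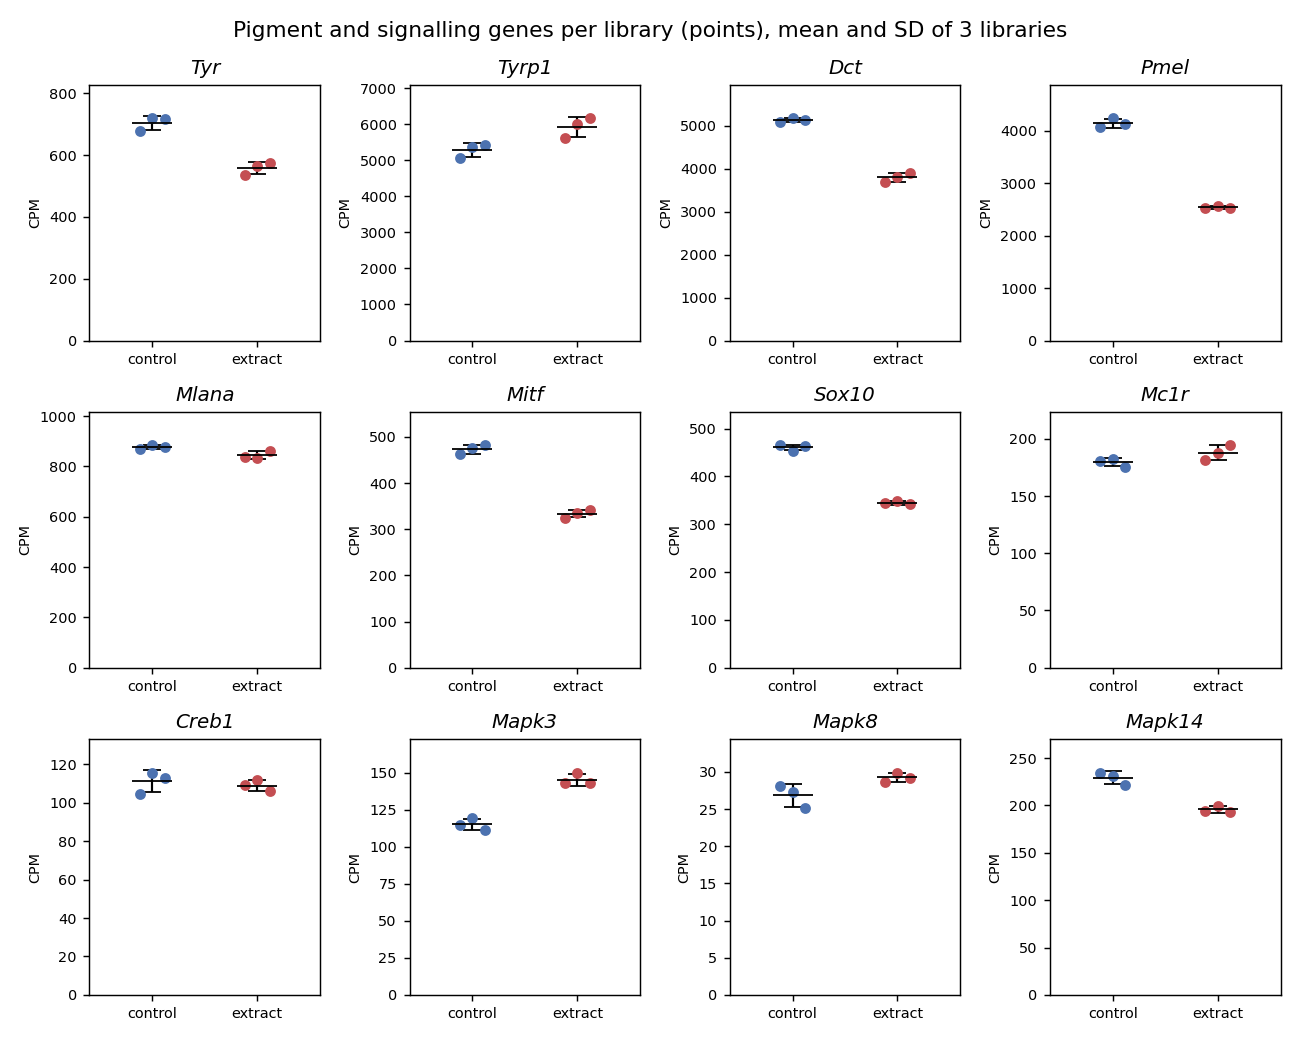
CPM (vertical axes, starting at 0) of 12 of the genes fixed in advance in control and extract-treated libraries, with each point 1 library and the black marks the mean and SD of 3 libraries. Pmel falls from 4145 to 2539 CPM and Mitf from 473 to 334 CPM with no overlap of the groups, while Tyrp1 rises and Mc1r and Creb1 overlap.

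Of 18 genes for melanin synthesis and melanosome proteins, 12 fell, 3 rose and 3 did not pass (12 and 4 adjusted over the list alone), and the list was lower than other genes (camera adjusted p = 3.57e-04; adjusted p = 0.202 with an estimated correlation). Besides Pmel and Dct, the melanosomal transporter gene Slc45a2 fell by 0.41 on the log2 scale and the ocular albinism gene Gpr143 fell by 0.57. The list's call was also lost with level-dependent offsets (camera adjusted p = 0.0804). Of 26 genes for melanosome biogenesis and transport, 14 fell and 3 rose (14 and 4 adjusted over the list alone), with a camera adjusted p = 0.00114 (adjusted p = 0.126 with an estimated correlation). Rab27a, Mlph and Myo5a, which together tether melanosomes to actin, fell by 0.63, 0.37 and 0.29 on the log2 scale. Hps3, a gene of Hermansky-Pudlak syndrome, fell by 0.59, and Rabggta, which encodes a subunit of the enzyme that prenylates Rab proteins, fell by 0.93. Of 16 tested pigment cell transcription factor and receptor genes, 8 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00291; adjusted p = 0.0705 with an estimated correlation). The neuregulin receptor gene Erbb3 fell by 0.77 and Pax3 by 0.37 on the log2 scale. The gene that rose was Snai2, a neural crest transcription factor gene, with a log2 fold change of 0.56 ± 0.14 (edgeR adjusted p = 0.00164).

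Genes of the cAMP/CREB pathway went both ways. Of 25 tested components, 6 rose, 5 fell and 14 did not pass, with the same counts adjusted over the list alone, and the list did not differ from other genes (camera adjusted p = 0.443), its median log2 fold change being -0.002 and its mean 0.02. Akap12, which encodes a scaffold of protein kinase A, rose from 33.6 ± 1.61 to 64.5 ± 0.604 CPM (log2 fold change 0.94 ± 0.04, edgeR adjusted p = 1.73e-14), and the adenylate cyclase gene Adcy7 rose by 0.29 ± 0.03. The adenylate cyclase gene Adcy2 fell by 0.79 ± 0.19, and the regulatory subunit gene Prkar2a fell by 0.25 ± 0.03. Creb1 (ENSMUSG00000025958) measured 111 ± 5.72 CPM in control and 109 ± 2.79 CPM in treated libraries, a log2 fold change of -0.03 ± 0.03 (edgeR adjusted p = 0.528) whose sign depended on the scaling. Of 23 genes known to respond to cAMP and CREB, 12 rose and 2 fell (14 and 2 adjusted over the list alone), with a median log2 fold change of 0.35 (camera adjusted p = 6.09e-04; adjusted p = 0.0668 with an estimated correlation). Irs2 rose by 1.05 ± 0.08, Atf3 by 1.04 ± 0.05, Junb by 0.56 ± 0.07 and Ppargc1a by 0.35 ± 0.04 on the log2 scale. Several of these, such as Atf3, Junb and Fosb, are also targets of other stimuli and stand on other lists.

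Components of the MAPK pathways also went both ways, while most tested genes on the lists of ERK, JNK and p38 responses rose. Of 32 components, 8 rose and 11 fell, with the same counts adjusted over the list alone, and the list did not differ from other genes (median log2 fold change -0.04, or 0.07 with level-dependent offsets, camera adjusted p = 0.689). Mapk3 (ENSMUSG00000063065), which encodes ERK1, rose from 115 ± 3.84 to 145 ± 4.08 CPM (log2 fold change 0.34 ± 0.03, edgeR adjusted p = 2.35e-09). Mapk14 (ENSMUSG00000053436), which encodes p38 alpha, fell from 229 ± 6.80 to 196 ± 3.37 CPM (log2 fold change -0.23 ± 0.03, edgeR adjusted p = 2.13e-07). Mapk8 (ENSMUSG00000021936), which encodes JNK1, had a log2 fold change of 0.12 ± 0.06 (edgeR adjusted p = 0.0824) and passed without control replicate 1 (edgeR adjusted p = 0.0457), with the filter at 1 CPM (0.0418) and with library totals (0.00583, log2 fold change 0.20). The kinase gene Map2k2 fell by 0.44 and the GTPase gene Hras fell by 0.41 on the log2 scale.

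Of 25 tested genes known to respond to ERK, 22 rose, 2 fell and 1 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.71 (camera adjusted p = 9.65e-13; adjusted p = 0.0344 with an estimated correlation). Etv5 and Etv4, transcription factor genes that report ERK activity, rose by 2.07 ± 0.10 and 2.35 ± 0.18, Egr1 rose by 2.61 ± 0.21 from 0.633 CPM, and Spry4 and Dusp6, which encode feedback inhibitors of the pathway, rose by 1.55 ± 0.15 and 0.61 ± 0.04 on the log2 scale. The JNK, p38 and AP-1 stress list had all 21 of its genes higher, also when adjusted over the list alone, with a median log2 fold change of 0.88 (camera adjusted p = 2.61e-25; adjusted p = 0.0154 with an estimated correlation). Several of these genes, such as Atf3, Junb, Fosb, Dusp1 and Btg2, also stand on the cAMP responsive or p53 lists. The rise of the list is therefore not specific to JNK and p38. Gadd45a, a growth arrest gene, rose from 13.5 ± 0.763 to 50.1 ± 3.36 CPM (log2 fold change 1.90 ± 0.06, edgeR adjusted p = 7.35e-17), and the AP-1 subunit gene Fosl2 rose by 1.10 ± 0.05. Of 18 tested genes responding to YAP or SRF, 15 rose and 3 did not pass, also when adjusted over the list alone (median log2 fold change 0.63, camera adjusted p = 2.46e-29; adjusted p = 0.00766 with an estimated correlation). In that list Ccn1, a matricellular protein gene, rose by 2.56 ± 0.05, and the actin-binding protein genes Cnn2, Zyx and Flna rose by 1.80, 1.06 and 0.46 on the log2 scale.

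Cholesterol genes rose nearly as a block. Of 26 genes of cholesterol synthesis and SREBP2 targets, 24 rose, 1 fell and 1 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of 0.56 (camera adjusted p = 2.37e-32; adjusted p = 0.0311 with an estimated correlation). Hmgcs1, an early enzyme gene of the pathway, rose from 68.9 ± 2.92 to 154 ± 2.79 CPM (log2 fold change 1.16 ± 0.03, edgeR adjusted p = 3.00e-18), and Insig1, which encodes a regulator of SREBP processing, rose by 1.14 ± 0.03. Fatty acid synthesis genes were mixed: 8 of 18 rose and 5 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.173), a list that did pass with library totals (camera adjusted p = 0.0398) and with level-dependent offsets (camera adjusted p = 0.00217). Scd1, Elovl6 and Fasn rose by 0.34, 0.38 and 0.28, while Srebf1 fell by 0.48 on the log2 scale. Of 11 tested liver X receptor targets 5 rose, 5 fell and 1 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.994). In that list Apoe fell by 0.37 on the log2 scale, the median log2 fold change was -0.005 and the mean 0.05, and the test pointed up.

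Lists of stress responses were each tested against other genes and not against each other. Of 26 genes of the NRF2 oxidative stress response, 17 rose and 6 fell, with the same counts adjusted over the list alone (median log2 fold change 0.25, camera adjusted p = 2.11e-09; adjusted p = 0.0241 with an estimated correlation). The cystine transporter gene Slc7a11 rose from 94.9 ± 5.48 to 219 ± 4.14 CPM (log2 fold change 1.21 ± 0.03, edgeR adjusted p = 3.40e-18), the heme oxygenase gene Hmox1 rose by 1.18 ± 0.04, and Srxn1 rose by 1.14 ± 0.04. Of 22 tested genes of the unfolded protein response, 12 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0307; adjusted p = 0.116 with an estimated correlation). The chaperone gene Hspa5 rose from 903 ± 11.8 to 1602 ± 41.3 CPM (log2 fold change 0.83 ± 0.02, edgeR adjusted p = 1.07e-19) and Dnajb9 rose by 1.52 ± 0.06, whereas Calr and Herpud1 fell by 0.56 and 0.53. Of 25 tested genes of the integrated stress response, 13 fell and 6 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.00165; adjusted p = 0.450 with an estimated correlation; camera adjusted p = 0.0740 with level-dependent offsets). The median of that list was -0.22, or -0.10 with level-dependent offsets, while its mean was 1.45e-05. A mean that small turns below 0 without any 1 of the larger risers. Without Fgf21, a hormone gene that rose by 2.18 ± 0.61 from 0.0894 to 0.407 CPM, the mean of the other 24 genes was -0.09. In the same list Slc7a11, Aldh1l2 and Ppp1r15a rose by 1.21, 1.12 and 1.03 and Chac1 and the amino acid transporter gene Slc7a5 fell by 0.84 and 0.77. Of 18 tested heat shock genes, 8 rose and 7 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.493). Its median and mean were 0.01 and 0.08 while its test pointed down, with Hsp90ab1 falling by 0.38 and Hspa8 rising by 0.35. Metal response genes were split, 5 up and 5 down of 11 tested, with the same counts adjusted over the list alone (camera adjusted p = 0.0185; adjusted p = 0.114 with an estimated correlation). The iron exporter gene Slc40a1 rose by 1.21 ± 0.09 and the metallothionein gene Mt1 fell by 0.78 ± 0.03 on the log2 scale.

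Genes of cell division fell together. Of 30 S phase genes 25 fell and 5 did not pass (26 fell adjusted over the list alone), with a median log2 fold change of -0.32 (camera adjusted p = 1.14e-14; adjusted p = 0.0705 with an estimated correlation). The replicative helicase genes Mcm6, Mcm5 and Mcm2 fell by 0.60, 0.62 and 0.52, and the thymidylate synthase gene Tyms fell from 97.1 ± 3.29 to 57.1 ± 4.43 CPM (log2 fold change -0.77 ± 0.04, edgeR adjusted p = 8.92e-13). Of 30 mitotic genes 28 fell and 2 did not pass, with the same counts adjusted over the list alone and a median log2 fold change of -0.28 (camera adjusted p = 2.25e-11; adjusted p = 0.110 with an estimated correlation). The topoisomerase gene Top2a fell by 0.44 and the mitotic kinase genes Plk1 and Aurkb by 0.49 and 0.44. Of 20 tested p53 targets 9 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0214; adjusted p = 0.170 with an estimated correlation). Plk2 rose from 19.8 ± 0.985 to 74.5 ± 3.57 CPM (log2 fold change 1.91 ± 0.05, edgeR adjusted p = 8.15e-19), Btg2 rose by 1.12 ± 0.10, and Sesn2 fell by 0.87 ± 0.04. Of 19 tested apoptosis regulators 10 rose and 3 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.0267; adjusted p = 0.116 with an estimated correlation). The death-promoting genes Bmf rose from 7.73 to 15.4 CPM and Bbc3 rose by 0.83 on the log2 scale, while Bak1, which also promotes death, fell by 0.48 on the log2 scale and the death inhibitor gene Cflar rose by 0.31.

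Of 3 metabolic lists, none passed with an estimated correlation. That correlation was 0.39 for hypoxia and glycolysis, -0.0070 for the respiratory chain and 0.0069 for lysosome genes, against the preset 0.01. Of 33 hypoxia and glycolysis genes 23 rose and 3 fell (24 and 3 adjusted over the list alone), with a median log2 fold change of 0.23 (camera adjusted p = 4.05e-10; adjusted p = 0.172 with an estimated correlation). Pgk1, a glycolytic enzyme gene, rose from 3109 ± 86.9 to 4451 ± 13.1 CPM (log2 fold change 0.52 ± 0.01, edgeR adjusted p = 6.84e-18), and Car9 and Ndrg1 rose by 0.96 and 0.79. Of 31 nuclear genes of the mitochondrial respiratory chain 20 fell and 6 rose (21 and 6 adjusted over the list alone), with a camera adjusted p = 0.00636 (adjusted p = 0.0705 with an estimated correlation). This call was also lost with library totals (camera adjusted p = 0.0718) and with level-dependent offsets (camera adjusted p = 0.703). Uqcrc1, Cyc1 and Atp5a1 fell by 0.42, 0.38 and 0.34 on the log2 scale. Of 33 tested lysosome and autophagy genes 20 rose and 6 fell, with the same counts adjusted over the list alone (camera adjusted p = 3.76e-04; adjusted p = 0.0668 with an estimated correlation). The autophagy receptor gene Sqstm1 rose from 1021 ± 8.58 to 1594 ± 17.7 CPM (log2 fold change 0.64 ± 0.02, edgeR adjusted p = 5.55e-19), and Gabarapl1 and the cathepsin gene Ctsl rose by 0.64 and 0.44.

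Lists of matrix, dedifferentiation, interferon and inflammatory genes passed with more members higher than lower, and none of the 4 passed with an estimated correlation. That correlation was under the preset 0.01 for dedifferentiation and interferon genes (-0.057 and -0.022), and above it for matrix and NF-kB genes (0.079 and 0.016). Of 28 tested matrix and invasion genes 20 rose and 4 fell, with the same counts adjusted over the list alone (median log2 fold change 0.44, camera adjusted p = 3.70e-08; adjusted p = 0.0695 with an estimated correlation). Sparc and Fn1, which encode matrix proteins, rose by 0.58 and 0.66 and Timp3 by 0.72 on the log2 scale. Of 14 tested genes of a dedifferentiated melanoma state 9 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.26e-04; adjusted p = 0.0637 with an estimated correlation). Nes and the receptor kinase gene Axl rose by 0.74 and 0.66, Ngfr rose by 1.21 ± 0.16, and the gene that fell was Cdh1, at under 1 CPM. The call for Cdh1 was lost without control replicate 1 (edgeR adjusted p = 0.117), control replicate 3 (0.0536), treated replicate 1 (0.0805) or treated replicate 3 (0.0662) and in DESeq2 (0.0566). Of 28 tested interferon response genes 13 rose and 2 fell (14 and 2 adjusted over the list alone), with a camera adjusted p = 0.00149 (adjusted p = 0.0679 with an estimated correlation). The antigen presentation genes H2-K1 and B2m rose by 1.08 and 0.41 and the chemokine gene Cxcl10 by 0.80 on the log2 scale. Of 18 tested NF-kB and inflammatory genes 14 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 9.08e-04; adjusted p = 0.0705 with an estimated correlation). Relb, Cxcl1 and Csf1 rose by 1.07, 1.09 and 0.66.

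The Wnt list did not pass, with 4 of 10 tested genes higher and 1 lower (camera adjusted p = 0.173). There the beta-catenin gene Ctnnb1 fell by 0.46 ± 0.02 (edgeR adjusted p = 2.75e-16) while Ccnd1 rose by 0.53. The TGF-beta and BMP list had 8 genes higher and 2 lower of 15 (camera adjusted p = 0.197), with Tgfb1 rising by 0.70 and Id2 falling by 0.46. The aryl hydrocarbon receptor list had 5 higher and 2 lower of 10 (camera adjusted p = 0.412), with Ahr rising by 0.67 and Tiparp by 0.40. Counts for these 3 lists were the same when adjusted over the list alone. Markers of other cell types were few and low. Of 12 fibroblast markers 5 were tested and 3 rose, also when adjusted over the list alone (camera adjusted p = 0.210), among them Pdgfrb, from 13.3 to 20.2 CPM. Of 14 immune markers 4 were tested and 3 rose (3 rose and 1 fell adjusted over the list alone): Cd74, from 1.34 to 5.23 CPM, Cd68, from 3.25 to 7.56 CPM, and Lyz2, from 0.971 to 1.53 CPM. The call for Lyz2 was lost without control replicate 1 (edgeR adjusted p = 0.0555), control replicate 2 (0.155), treated replicate 1 (0.172) or treated replicate 3 (0.123), in DESeq2 (0.0750) and with level-dependent offsets (0.201). Of 11 endothelial markers 2 were tested and 1 rose, also when adjusted over the list alone, which was Vwf, from 1.41 to 3.08 CPM. Of 12 keratinocyte markers 0 passed the expression filter.

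**Figure D2:**
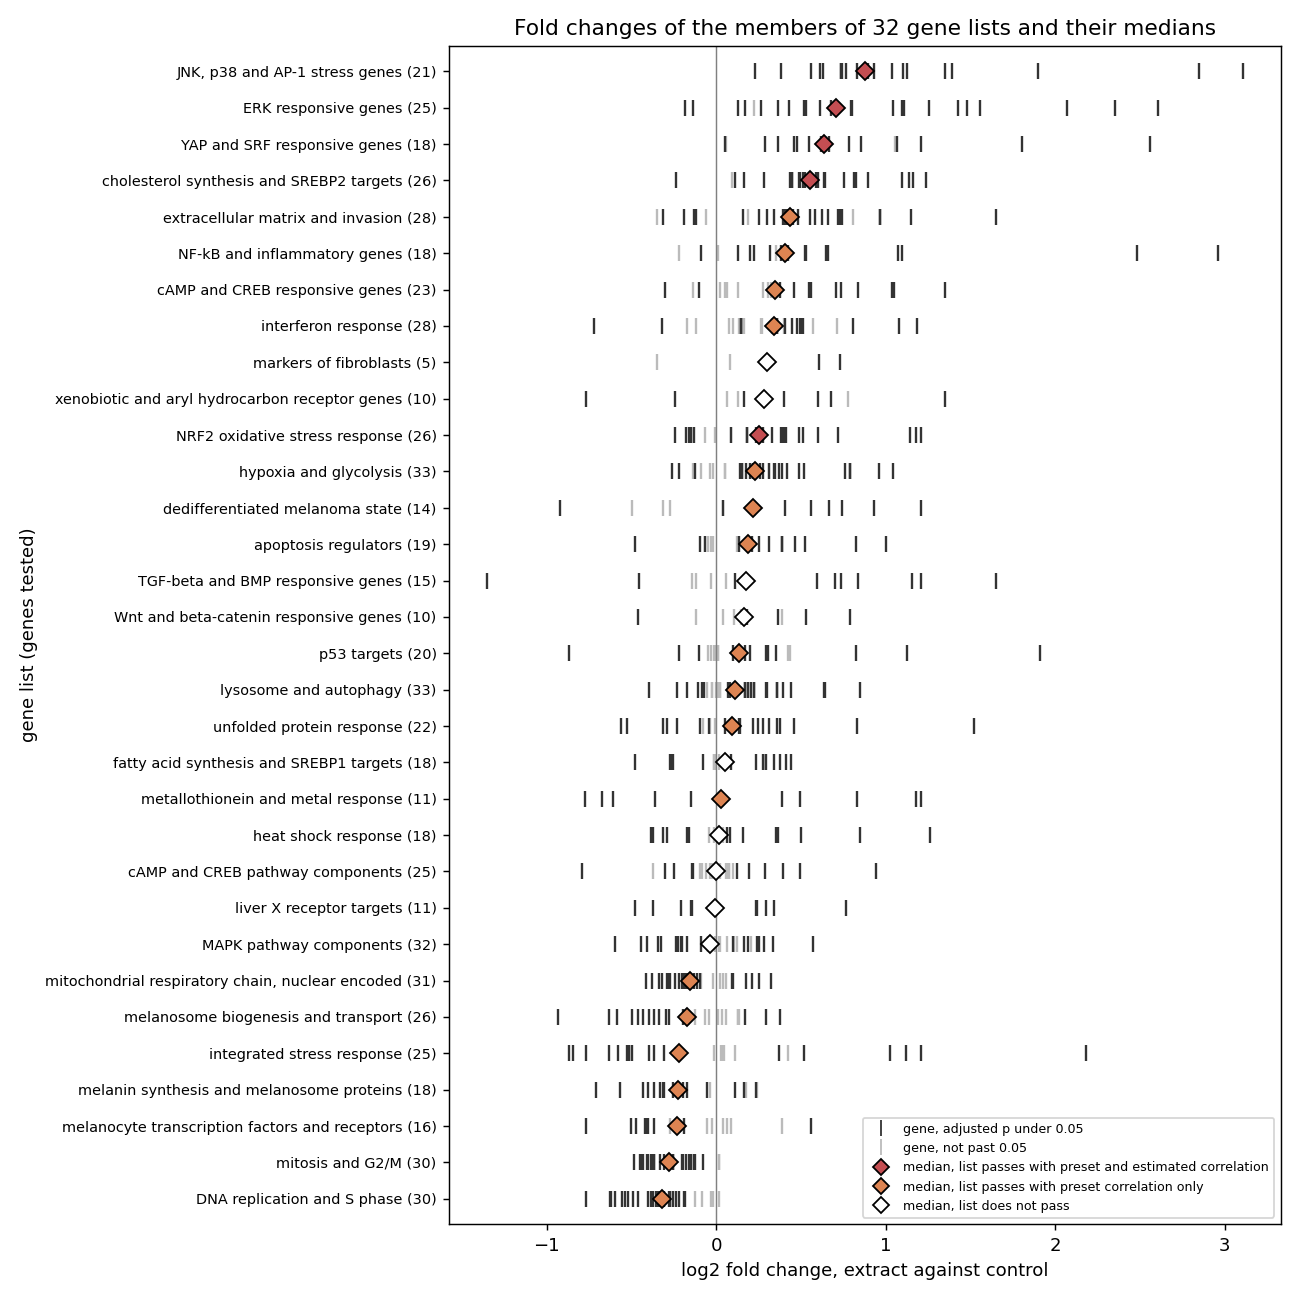
Log2 fold change (horizontal axis, treated against control) of each tested gene in 32 gene lists, each tick 1 gene, dark where its adjusted p is under 0.05, with diamonds at list medians coloured by whether the list passed. The medians run from -0.32 for S phase genes to 0.88 for JNK, p38 and AP-1 stress genes, and 5 lists pass with both the preset and the estimated correlation.

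Some members moved against a list that passed, and these are named after their values were seen. Oca2, a melanosomal transporter gene, and Gpnmb rose by 0.23 and 0.11 on the log2 scale among the pigment protein genes, and Sytl2, Hps1 and Bloc1s6 rose by 0.38, 0.30 and 0.17 among the melanosome transport genes. Crtc1, which encodes a coactivator of CREB, fell by 0.30, Ebp of cholesterol synthesis by 0.24, Slc2a3, a glucose transporter gene, by 0.26, and Ddit4, which stands on the p53 and the hypoxia list, by 0.22. Nr4a3, Phlda1, Ier2, Ei24, Mcl1, Irf9, Sod2 and Hk2 had log2 fold changes between -0.32 and -0.07 that passed, and each lost its call with library totals, where Mcl1 turned to 0.01, while Hk2 turned to 0.02 with level-dependent offsets. Of these 8 genes, all but Phlda1 and Hk2 also lost the call without at least 1 library.

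The largest rises among protein-coding genes of at least 5 CPM were those of Sh2d6 (ENSMUSG00000052631), from 0.506 ± 0.213 to 13.3 ± 0.895 CPM (log2 fold change 4.67 ± 0.17, edgeR adjusted p = 4.37e-16), and the transcription factor gene Klf2 (ENSMUSG00000055148), from 1.06 ± 0.268 to 9.20 ± 1.11 CPM (log2 fold change 3.11 ± 0.16, edgeR adjusted p = 2.83e-13). Next came Cdsn (ENSMUSG00000039518), which encodes the skin adhesion protein corneodesmosin, with a log2 fold change of 3.01 ± 0.12, and Klf4 (ENSMUSG00000003032), with 2.85 ± 0.09. Ccn1 (ENSMUSG00000028195) rose 5.89-fold, the natriuretic peptide gene Nppb (ENSMUSG00000029019) 4.70-fold, the interferon-induced exonuclease gene Isg20 (ENSMUSG00000039236) 4.49-fold and Etv5 (ENSMUSG00000013089) 4.19-fold. The largest fall was that of Enpp2 (ENSMUSG00000022425), which encodes autotaxin, the enzyme that makes lysophosphatidic acid, from 116 ± 4.62 to 39.4 ± 0.261 CPM (log2 fold change -1.55 ± 0.04, edgeR adjusted p = 2.15e-19). The lipid transporter gene Abca12 (ENSMUSG00000050296) fell by 1.37 ± 0.06 on the log2 scale, and Pmepa1 (ENSMUSG00000038400), a TGF-beta target, fell by 1.35 ± 0.12. Ass1 (ENSMUSG00000076441), which encodes argininosuccinate synthase of arginine synthesis, fell by 1.11 ± 0.05. The imprinted genes Mest (ENSMUSG00000051855) and Peg10 (ENSMUSG00000092035) fell by 1.11 ± 0.07 and 1.09 ± 0.03. Ccdc13 (ENSMUSG00000079235) and Insc (ENSMUSG00000048782), the gene of an adaptor in oriented cell division, fell by 1.09 ± 0.09 and 1.05 ± 0.03. The rule that chose these 16 genes required groups that did not overlap.

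Expression level and fold change were related. The median log2 fold change was 0.29 among genes with a mean under 0.5 CPM and -0.16 among those over 250 CPM, among 15150 tested genes. The size of the fall depended on the scaling. For 685 protein-coding genes over 250 CPM the median fall was 10.5% under TMM and 5.53% with library totals. Set among 10000 random lists matched on expression level, the median of the pigment protein list lay at percentile 3.10, that of the respiratory chain list at 22.8, and that of the cholesterol list at 100. Several library measures moved with the groups. Treated libraries had more genes with at least 1 count, 21658 ± 301 against 20897 ± 262 (SD, n = 3 per group), a larger mitochondrial share, 3.08% against 2.91%, and a smaller ribosomal protein share, 3.90% against 4.26%. Each of these 3 differences had no overlap and a two-sided exact permutation p = 0.1, the smallest that 3 against 3 can give (0.111 with Benjamini-Hochberg adjustment over 10 library measures).

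**Figure D3:**
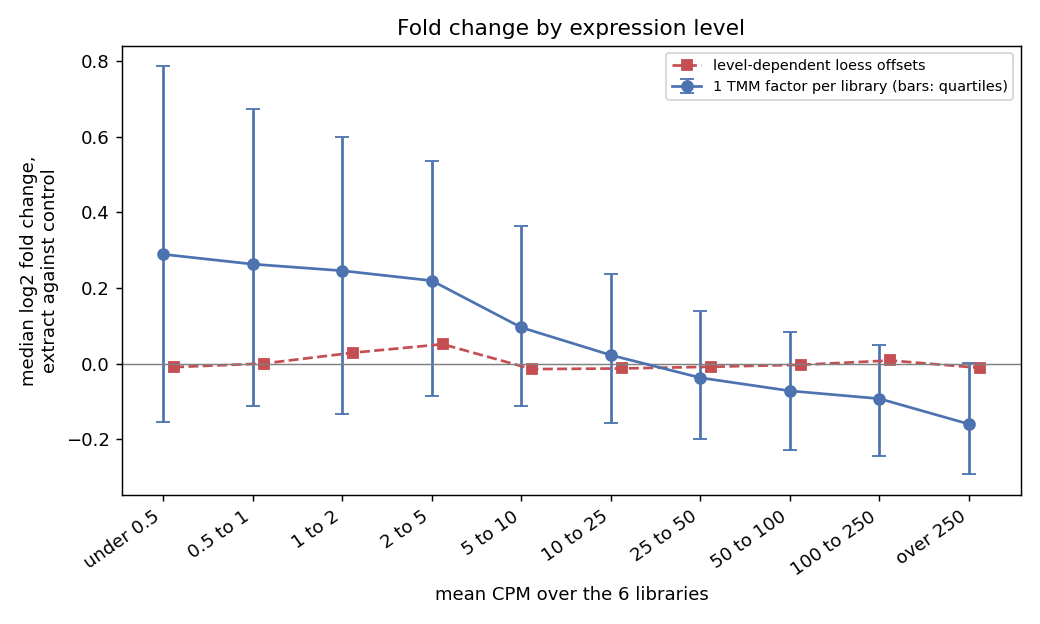
Median log2 fold change (vertical axis, treated against control) by class of mean CPM over the 6 libraries, with 1 TMM factor per library (circles, bars showing the quartiles across genes) and with level-dependent loess offsets (squares). With TMM the medians go from 0.29 in the lowest class to -0.16 in the highest, and with loess offsets they lie between -0.01 and 0.05.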

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

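The tests for genomic DNA were chosen after the results were seen, the second comparison set among them after the first had left the question undecided, and the test of depth was set before its result was seen. The 11917 genes left out by the expression filter, which the comparison does not use, held more counts in treated libraries. They summed to 808 ± 29.1 CPM in treated and 638 ± 5.38 CPM in control libraries (SD, n = 3 per group), a ratio of 1.27 with no overlap, and the two-sided exact permutation p = 0.1 is the smallest that 3 against 3 can give.

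The same direction appeared in the medians of tested genes, where the log2 fold change was 0.29 under 0.5 CPM and -0.16 over 250 CPM. Single genes went both ways. Of 1195 genes under 0.5 CPM 163 passed as higher and 12 as lower, and of 693 over 250 CPM 141 and 476. Genomic DNA would add the same CPM per kb of exon everywhere, and 1657 unconfirmed or sense-intronic genes under 1 CPM gained 0.0106 ± 0.00255 CPM per kb (SE). Over all exons this would add 0.102% to the library, against a median fall of 5.53% for 685 protein-coding genes over 250 CPM under library totals, which argues against genomic DNA as the source of the fall. For the rise of genes with few counts it cannot be told apart: the gain was 0.700 ± 0.170 of that of all 4776 protein-coding genes under 1 CPM, which is within 2 SE of an equal gain, but 0.224 ± 0.0546 of that of the 990 tested ones, which the expression filter selects for higher levels. Library totals overlapped between the groups, at 31991473 to 40129044 in control and 31183728 to 33717357 in treated libraries. Thinning every library to the smallest total left the median log2 fold change of 2443 genes under 1 CPM at 0.27, as it was before. Thinning keeps the expected share of each gene in its library, so it could not remove a depth effect already in the counts and does not decide on depth. Also open are an effect of the treatment on the spread of expression, which was not tested apart from it, and any unrecorded difference in library preparation between the groups, although per the labels all RNA was extracted at the same time.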

How the results depend on the processing

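Level-dependent offsets were chosen after the data were seen, and all other alternatives before. The count of 8032 changed genes lay between 7389 and 8114 over all alternatives. With offsets 6547 of these calls were kept with their direction and 32 passed in the opposite direction, and with DESeq2 7408 were kept. Counts of at least 2-fold changes moved more: without a filter 83 genes were lower, with the filter at 1 CPM, which tests fewer low genes, 392 changed (362 higher, 30 lower), and with offsets 383 were higher and 149 lower. Leaving out single libraries gave 64 to 93 lower genes, the 93 without treated replicate 1. The replicate numbers did not pair the libraries: correlations of deviations were -0.01, -0.04 and 0.01, and 1 of 6 libraries correlated best with its own number. With the replicate number as a block 8061 genes changed, and apart from the sign of the liver X receptor list (camera adjusted p = 0.857) no call or direction of a list or named gene changed. Of 448 comparisons of 32 lists, 409 kept direction and side of the threshold. With an estimated correlation, adjusted p = 0.202 for pigment proteins, 0.126 for melanosome biogenesis, 0.0705 for pigment cell factors, S phase, NF-kB and the respiratory chain, 0.0668 for cAMP responsive and lysosome genes, 0.116 for the unfolded protein response and apoptosis, 0.450 for the integrated stress response, 0.110 for mitosis, 0.170 for p53, 0.0679 for interferon, 0.172 for hypoxia, 0.0695 for matrix, 0.0637 for dedifferentiation and 0.114 for metal response, against 5 lists that passed. For pigment cell factors, cAMP responsive genes, the unfolded protein response, apoptosis and interferon the estimated correlation was -0.040 to 0.0045, under the preset 0.01. So it was for the respiratory chain, lysosome genes, dedifferentiation and metal response, at -0.082 to 0.0069. A higher correlation therefore does not account for the loss of these calls. For the other lists that lost the call it was 0.016 to 0.47. With fry, a test of balance within the list, more lists passed: cAMP components and fatty acids at 0.0130, MAPK components 0.0197, Wnt 5.14e-04, TGF-beta 0.00403, aryl hydrocarbon receptor 0.0314, heat shock 0.00446 and fibroblast markers 0.0161, while liver X receptor targets turned down (0.549). With library totals fatty acids passed (0.0398), the respiratory chain did not (0.0718) and MAPK components turned up (0.895). With offsets fatty acids passed (0.00217), pigment proteins (0.0804), the integrated stress response (0.0740) and the respiratory chain (0.703) did not, and MAPK components (0.479) and heat shock (0.263) turned up without passing. Liver X receptor targets turned down without a filter (0.894), and over the single libraries left out their adjusted p was 0.717 to 0.969, turning down without treated replicate 2 (0.723). Of 2843 comparisons of 219 genes, 2765 kept direction and side, 60 lost and 9 gained a call, and 9 changed sign. Those that changed sign were Mlana (0.026 with library totals, 0.11 with offsets), Creb1 (0.051 and 0.062, and between -0.066 and 0.0010 with single libraries left out, above 0 without control replicate 2), Mcl1 (0.0097 and 0.044), and with offsets Prkar1a (0.0088) and Hk2 (0.018). The cause of these changes was not tested beyond the fewer genes or libraries in some fits. In the simulation low counts limited detection. Changes of 2-fold were recovered for 0 of 6 genes under 1 CPM and 42 of 44 others, 1.5-fold changes for 0 of 8 and 37 of 42, and 4-fold changes for all. The simulation changed 200 genes against 8032 called in the data, so its adjusted p threshold was stricter and these rates do not carry over. In the data 163 genes under 0.5 CPM passed as higher and 12 as lower, and 221 and 26 at 0.5 to 1 CPM.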

Other observations

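The gene families and genes below were chosen after the data were seen, as were both tests on ERK responsive genes, while the tests of the families against expression level and the splits of the libraries were set before their results were seen. Most tested members of 6 gene families, 5 of protein synthesis or turnover and 1 of RNA-binding and splicing proteins, fell under TMM. The family medians were below 0 also with median-of-ratios factors, library totals and level-dependent offsets. With library totals the falls were weaker, such as -0.11 against -0.19 for ribosomal proteins and -0.13 against -0.21 for hnRNP and SR proteins. With offsets 35 of 76 ribosomal protein genes were lower and 3 higher. The counts were 9 and 3 of 18 aminoacyl-tRNA synthetase genes, and 18 and 5 of 30 hnRNP and SR protein genes. Of 35 tested proteasome subunit genes 34 fell, with a median log2 fold change of -0.36, and the exception, Psmd8, rose by 0.57 ± 0.02 (edgeR adjusted p = 4.07e-15). Psmc5 and Psmc3, subunits of the regulatory particle, fell by 0.55 and 0.53 on the log2 scale. Of 20 nucleolar ribosome assembly genes 19 fell and Nop10 rose (median -0.38), with falls for Ncl, from 1842 to 1156 CPM, Npm1, from 1268 to 846 CPM, and Bop1, from 180 to 105 CPM. Of 77 mitochondrial ribosomal protein genes 63 fell and 4 rose (median -0.27), with Mrpl12 and Mrps7 falling by 0.48 and 0.53. Of 18 cytosolic aminoacyl-tRNA synthetase genes 15 fell (median -0.26), with Tars and Vars falling by 0.47 and 0.42. Of 30 hnRNP and SR protein genes 23 fell and 2 rose (median -0.21), with Hnrnpa1 falling from 912 to 573 CPM and Hnrnpab from 713 to 506 CPM. Of 76 ribosomal protein genes 69 fell (median -0.19), with Rpl8 and Rpl4 falling by 0.31 and 0.25.

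Because these are abundant genes, the trend of fold change with expression level may account for part of their fall. With level-dependent offsets the ribosomal protein median was -0.044, so the trend could account for most of that family's fall. The medians with offsets were -0.27 for proteasome subunits, -0.30 for nucleolar ribosome assembly, -0.23 for mitochondrial ribosomal proteins and -0.11 for hnRNP and SR proteins, each with an upper quartile below 0, which argues against the trend as the whole cause. The aminoacyl-tRNA synthetases, at -0.12 with an upper quartile of 0.02, cannot be told apart from the trend by this measure because their members then spread to both sides of 0. Among random lists matched on expression level, their median under TMM lay at percentile 1.71. That of hnRNP and SR proteins lay at 4.67, that of ribosomal proteins at 8.59 and those of the other families at 0. By that measure the synthetases departed from the trend at least as far as hnRNP and SR proteins. The families were chosen after the data were seen and the random lists were not, so low percentiles may follow from that choice. They are therefore no test of the falls. That treated cells held less RNA for making and degrading proteins is a hypothesis that stays open, and no measure of growth or protein output was analysed here.

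The direction of the ERK responsive genes is of interest because the title of the series names an inhibition of MAPK signalling. The trend with expression level does not account for it, since the list median was 0.68 with level-dependent offsets (camera adjusted p = 3.39e-13, with a range over the alternatives from 1.94e-19 to 0.0344). Nor was the rise confined to immediate-early genes. A set of 15 members picked by hand as lying outside them, such as Dusp6, Spry4 and Etv5, rose with a median log2 fold change of 0.80. They were picked after their values were seen, and the pick left out Phlda1, which had a log2 fold change of -0.14. That all 15 rose is therefore no test of the remaining members. A higher ERK output at the time of sampling may be a candidate explanation, but mRNA levels do not measure phosphorylation, the time after treatment is not given in the sources used here, and a rebound after an earlier inhibition would look the same in these data.

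Mitochondrial transcripts did not move together, although their joint share was larger in treated libraries. The ribosomal RNA gene mt-Rnr1 rose by 0.62 ± 0.03 and mt-Co1 rose by 0.23 ± 0.01, while mt-Cytb fell by 0.44 ± 0.02 on the log2 scale. The linker histone gene Hist1h1c rose from 19.1 ± 1.06 to 46.1 ± 3.10 CPM while S phase genes fell. The other 42 protein-coding genes with symbols beginning in Hist together held 27.8 to 30.3 CPM in control and 34.9 to 36.6 CPM in treated libraries. Histone genes under other symbols were not counted. The libraries were of polyadenylated RNA, so these sums do not measure histone mRNA without a poly(A) tail.

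The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split was the 1 split of the 10 that gave as many changed genes, 8032, and as many genes changed by at least 2-fold, 682. In edgeR the highest counts among the other splits were 0 and 0, with at most 176 genes at an unadjusted p under 0.05 against 8746 in the real split. For gene lists the real split passed 23 and was again the 1 split with as many, and the highest of the others passed 14. Each other split puts 1 library of a group with 2 of the other, so that part of the treatment difference remains in it. The treatment difference then also enters the spread within each side of the split, which by itself lowers the counts of genes. The counts of 0 and 0 therefore do not show what splits without a treatment difference would give.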
